A study of Homo sapiens with 2 samples.

How the data were processed

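SAS cells, an established line of head and neck squamous cell carcinoma, were cultured as spheres for about 4 weeks in serum-free medium with N2 supplement, basic FGF and EGF at 10 ng/mL each, per the labels' protocols. Cells were stained with DCFDA, a dye that becomes fluorescent when oxidised, and sorted into ROSLow and ROSHigh fractions. Total RNA was extracted with TRIzol, reverse transcribed with random hexamers and sequenced as paired-end reads of 100 bp, per the labels' protocols. Each fraction gave 1 library. The aligner, the counting program and the strandedness are not given in the sources used here.

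The deposited tables hold, per the file headers, total and unique transcript read counts for each transcript, and the authors' RPKM values (read counts corrected for transcript length and for the total of mapped reads). The total counts are whole numbers and were used for all main results, and the RPKM values entered 1 alternative. The genome build is GRCh38 per the submitters' processing notes, and 99.97% of 18285 gene names found once in GENCODE 29 overlapped the GENCODE gene of that name on this build. The tables list 67765 RefSeq transcripts on 22 autosomes and the X and Y chromosomes. Mitochondrially encoded genes and ribosomal RNA were not analysed here. Counts of the transcripts of a gene were summed to 19781 genes. Of the gene names, 26 had been turned into calendar dates, as spreadsheets do; names that could be recovered from RefSeq accessions were restored, and 17 that could not, with 47 transcript rows, were left out, at 0.0536% of the reads in ROSLow and 0.0477% in ROSHigh.

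The depth was 50262800 transcript reads in ROSLow and 37519871 in ROSHigh, of which 33.19% and 32.55% were unique to a transcript in the authors' tables. Reads unique to a transcript leave out reads shared between transcripts of the same gene, so they need not follow the total of the gene. The total of mapped reads behind the RPKM values, recovered from counts, lengths and RPKM, was 59812869 and 51905098. PCR copies were not told apart from separate molecules, so intervals cover counting error only. How the 2 reads of a pair were counted is not given in the sources used here. Of the genes with 11 to 100 reads, 49.3% in ROSLow and 50.5% in ROSHigh had an odd count, so not every pair was counted as 2 reads; where both were counted, the intervals are too narrow.

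Counts were scaled to the total over named genes, and log2 ratios of ROSHigh to ROSLow were computed with 0.5 count added to each library. Genes with at least 20 reads over both libraries were kept. A gene was called higher or lower where the ratio was at least 2 or at most 0.5 and the exact 95% conditional interval of the ratio excluded 1. This compares 2 libraries and not the conditions, since neither fraction was replicated, and it is a description with no p-value. The genes to name were fixed before the data were examined: the 12 highest and 12 lowest ratios among genes with at least 100 reads whose interval excluded 1, without Y-linked, small RNA, clone-named or antisense genes, and in addition up to 4 members of each gene list with the largest absolute log2 ratio and every measured member of the superoxide and peroxide removal list. Lists were 38 in number, and 740 of their 755 symbols were matched to the tables. For each list with at least 5 measured members the median log2 ratio was placed among the medians of 10000 random lists in which each member was replaced by a gene from the same of 20 bins of mean expression. Genes that share sequence with close copies (ALPP, HSPA1B, the histone, keratin and metallothionein families) are uncertain, because how the authors' counting split such reads is not given in the sources used here.

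Alternatives fixed beforehand were TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, no count minimum, a minimum of 100 reads, 5 counts added, unique reads, the authors' RPKM values with 1 added and a mean of at least 1, a ratio of 3, no condition on the interval, and random lists matched on expression and length in 10 by 10 bins. Alternatives chosen after seeing the data were the mapped-read totals behind the RPKM values, removal of the running median over transcript length or GC content in windows of 501 genes, a mean of at least 10 CPM, and random thinning of ROSLow to the ROSHigh total. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and in R 4.3.3.

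The calling rule was tested on simulated Poisson counts for 19781 genes with the abundances and totals of these libraries and 200 genes with a set change. The 200 genes were drawn from genes with at least 100 expected reads over both libraries, so calls on scarcer changed genes were not tested. It called 100% of 50 genes set 3-fold higher, 100% of 50 set 6-fold higher and 100% of 50 set 3-fold lower, and 0% of 50 genes set 1.5-fold higher. Among 13241 unchanged genes past the minimum, 41 were called. Of 200 random lists, 4.5% fell outside the central 95%. These simulations hold no biological or handling variation.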

Results

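RNA was sequenced from SAS cells, an established human tongue squamous cell carcinoma line, that had been grown as spheres and then sorted by flow cytometry on their content of reactive oxygen species (ROS), read out with the dye DCFDA. Cells with a low signal (ROSLow) and cells with a high signal (ROSHigh) each gave 1 library, so the comparison asks which transcripts differed in abundance between the low and the high fraction of the same sphere culture. The ROSLow library held 50262800 transcript reads and the ROSHigh library 37519871. Reads were found for 15603 genes in ROSLow and for 16114 in ROSHigh. With 1 library per fraction there was no spread between replicates, no p-value was computed, and every difference below is between these 2 libraries. The 95% intervals given with ratios are exact conditional (Clopper-Pearson) intervals that cover counting error only, and they are too narrow if both reads of a pair were counted.

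The most divergent transcripts separated the fractions by more than 10-fold in either direction. ATOH8, a basic helix-loop-helix transcription factor (chromosome 2, 85753786 to 85791383, GRCh38), had 3 reads in ROSLow and 902 in ROSHigh, a ratio of 403 with an interval of 137 to 1957. ID1 and ID3, which encode inhibitors of basic helix-loop-helix factors, were 32.2-fold (29.3 to 35.4) and 51.2-fold (39.3 to 67.8) higher in ROSHigh, and ID1 (chromosome 20, 31605283 to 31606515) reached 285 CPM (counts scaled to the library total) there against 8.86 CPM in ROSLow. In the opposite direction, KISS1, the kisspeptin precursor gene (chromosome 1, 204190341 to 204196491), was 22.5-fold lower in ROSHigh with an interval of 16.8 to 30.7. The ETS-family transcription factor genes ETV4, ETV5 and ETV1 were 13.6-fold, 10.0-fold and 10.1-fold lower, with 3761 reads of ETV4 in ROSLow and 206 in ROSHigh.

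Among genes with at least 100 reads over both libraries, the 12 highest ratios in ROSHigh further included CFI, the complement factor I protease gene, with 1 read in ROSLow and 180 in ROSHigh, and FAM198B with 1 and 121 reads. The ratio of CFI was 241 and its interval ran from 42.7 to 9576, so its size was poorly defined. COL1A2, which encodes a chain of type I collagen, was 54.5-fold higher (18.2 to 268), and NPNT, the gene of the matrix protein nephronectin, was 38.2-fold higher (14.5 to 143). The remaining genes were IGFN1 at 49.0-fold, ALPP at 39.0-fold, KIAA1683 at 34.3-fold, STRA6 at 32.8-fold and SYT8 at 31.5-fold. ALPP shares much of its sequence with other alkaline phosphatase genes, and its assignment is uncertain. The 12 lowest ratios further included RGCC, a regulator of cell cycle, at 15.9-fold lower in ROSHigh, ESM1 at 15.4-fold and ANGPTL4 at 11.3-fold. The cytokine genes TNFSF15 and LTB were 11.0-fold and 10.7-fold lower. C10orf10, PALM2 and PIK3IP1 were 9.63-fold, 9.52-fold and 8.96-fold lower.

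**Figure D1:**
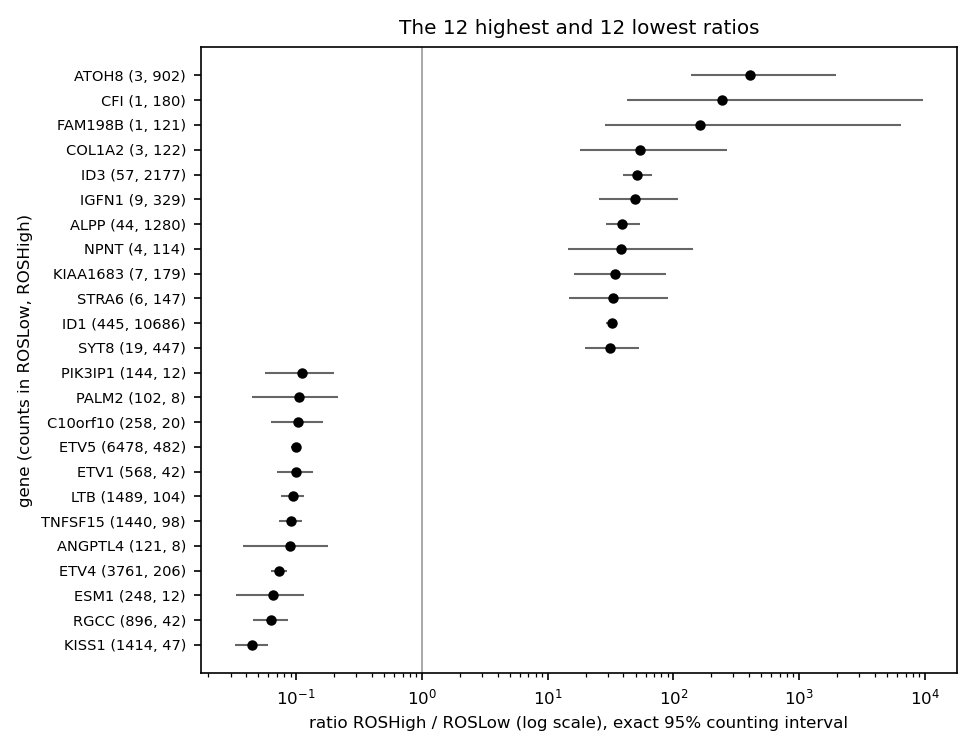
Ratio of ROSHigh to ROSLow on a log scale for the 12 genes with the highest and the 12 with the lowest ratio, with the reads in ROSLow and ROSHigh in parentheses; points are ratios and bars are exact 95% counting intervals from 1 library per fraction. The ratios run from 0.0445 for KISS1 to 403 for ATOH8, and the bars are widest for genes with 1 to 4 reads in ROSLow.

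Of 13399 genes with at least 20 reads over both libraries, 2038 were at least 2-fold higher in ROSHigh and 329 were at least 2-fold lower, each with a counting interval that excluded 1. This split depended on the scaling between the libraries. Scaled to the library totals, 86.1% of these genes were higher in ROSHigh, against 73.6% (1611 higher and 579 lower) with TMM factors, 72.1% (1576 and 610) with DESeq2 size factors and 69.0% (1517 and 680) with the mapped-read totals behind the authors' RPKM values. The authors' RPKM values themselves, with 1 added before the log, gave 372 higher and 354 lower among 10793 genes with a mean of at least 1. These values share the mapped-read totals that gave 1517 higher and 680 lower, so the further fall is not one of scaling. The 1 added, the minimum, the length correction and the missing interval condition also differ there. The median log2 ratio of all genes was 0.135 with library totals and -0.03, -0.049 and -0.082 with the other 3 scalings. The excess sat mainly among scarce transcripts: the median log2 ratio was 0.921 in the decile of genes with the lowest abundance and -0.064 in the decile with the highest.

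**Figure D2:**
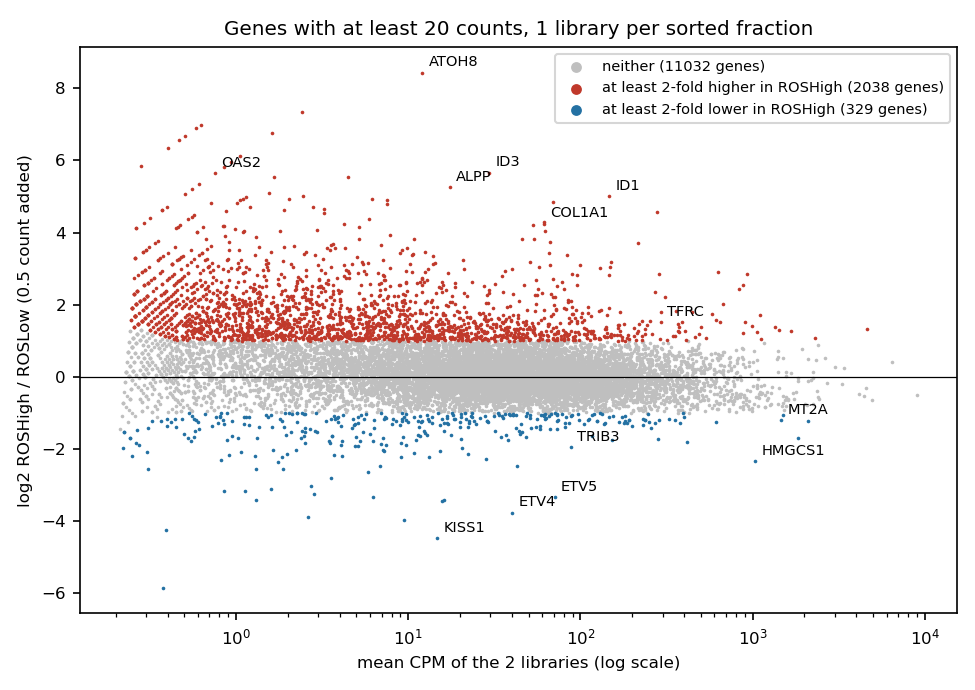
Log2 ratio of ROSHigh to ROSLow (0.5 count added) against the mean abundance of the 2 libraries in CPM on a log scale; each point is a gene with at least 20 reads, red at least 2-fold higher in ROSHigh (2038 genes), blue at least 2-fold lower (329 genes) and grey neither. The red points are densest at low abundance, and HMGCS1, ETV5 and MT2A lie among the abundant genes that were lower.

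Gene lists fixed before the data were examined were described by the median log2 ratio of their members and by its percentile among 10000 random lists of the same size matched on mean expression. Of 35 lists with at least 5 measured members, 10 lay below and 7 above the central 95% of random lists. The medians of 13 lists changed sign under at least 1 alternative, and no direction is drawn from them: NRF2 targets, glutathione genes, NADPH oxidases, iron handling, heat shock, mesenchymal genes, epithelial junctions, p53 targets, FOXO targets, apoptosis regulators, fatty acid genes, the NF-kB list and endothelial markers. Of 20 measured genes that remove superoxide and peroxides, 15 had a log2 ratio below 0, the median was -0.25, and the percentile was 1.87. GPX1, the main cytosolic glutathione peroxidase gene (chromosome 3, 49357176 to 49358358), was 2.10-fold lower (2.03 to 2.18), at 246 CPM in ROSLow and 117 CPM in ROSHigh. TXN was 1.70-fold, PRDX6 1.53-fold, SOD2 1.46-fold and PRDX1 1.45-fold lower, below the 2-fold limit. GPX3 was the only member past 2-fold higher, on 13 and 22 reads. GPX4 had a log2 ratio of 0.24, and that of catalase, CAT, was 0.12 and changed sign under the other scalings. Against random lists matched on transcript length as well as expression, the percentile of this list was 36.69, inside the central 95%, and 4 further alternatives also brought it inside; with the length trend removed the median was -0.079. GPX3 came below 2-fold under the other scalings.

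NRF2 target genes did not stand apart, with a median of 0.18 at percentile 65.02 and 4 of 22 measured members at least 2-fold higher. Among them ABCC3, a multidrug resistance transporter gene, was 10.8-fold higher (9.92 to 11.9) in ROSHigh, and EPHX1 was 2.49-fold higher. TRIM16L, also among the 4, came below 2-fold under the other scalings. Genes of glutathione synthesis and glutathione S-transferases had a median of 0.20 at percentile 59.08, and CHAC1, which encodes a glutathione-degrading enzyme, was the only one of 15 past the limit, 4.19-fold lower. The median of this list was -0.21 with unique reads and -0.45 with the authors' RPKM values. GSTO1, 1.80-fold lower, was past 2-fold lower under the other scalings. NADPH oxidases and other oxidases had a median of 0.85 at percentile 96.74, and 5 of 12 were at least 2-fold higher; the percentile was 98.77 after removal of the length trend, and the median was -0.10 with the authors' RPKM values. NOXA1, an activator of NADPH oxidase 1, was 5.99-fold higher (4.80 to 7.55) and DUOX1 4.80-fold higher, whereas NOX5 rested on 35 reads in ROSHigh. Of the 5 metallothioneins measured, MT2A was 2.29-fold lower and MT1F 2.11-fold higher, and the list median of -0.47 lay at percentile 2.69. That percentile was 1.73 with no count minimum, 2.21 with 5 counts added and 1.30 with the GC trend removed, outside the central 95%. MT1F came below 2-fold under the other scalings. For iron handling the median was 0.13 at percentile 76.5, and 98.1 after removal of the length trend, with TFRC, the transferrin receptor gene, 2.88-fold higher (2.80 to 2.95).

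Sterol synthesis and hypoxia genes showed the lowest list medians in ROSHigh. Of 21 measured cholesterol synthesis genes, 8 were at least 2-fold lower and 20 had a ratio below 1, and the median log2 ratio of -0.85, or 1.81-fold lower, lay below all 10000 random medians. HMGCS1, which makes the substrate of HMG-CoA reductase (chromosome 5, 43287470 to 43313512), was 5.06-fold lower (4.97 to 5.16), INSIG1 3.50-fold, MSMO1 2.56-fold and FDPS 2.55-fold. Of 22 hypoxia response genes, 7 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.83 below all 10000 random medians; HILPDA was 3.91-fold, EGLN3 3.04-fold and MXI1 2.65-fold lower. Glycolysis genes had a median of -0.37 at percentile 0.82, and 2 of 22 were past the limit: SLC2A3, a glucose transporter gene, 3.38-fold lower and HK2 2.10-fold lower. The glycolysis percentile was 3.98 with the authors' RPKM values and 2.81 after removal of the length trend, inside the central 95% in both cases. Fatty acid synthesis and oxidation had a median of 0.16 at percentile 85.93, and SREBF1 was 2.19-fold higher, though below 2-fold under the other scalings.

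Stress response lists differed in direction. Of 22 genes of the ATF4 and integrated stress response, 8 were at least 2-fold lower and 2 at least 2-fold higher in ROSHigh, with a median of -0.53 below all 10000 random medians; TRIB3 was 3.87-fold, DDIT4 3.31-fold and the serine synthesis gene PSAT1 3.11-fold lower, while NUPR1 was 8.93-fold higher on 20 reads in ROSHigh. Endoplasmic reticulum chaperones of the unfolded protein response had a median of 0.46 at percentile 99.89, with 18 of 20 above 0 and none past 2-fold; CALR was 1.92-fold and PDIA4 1.78-fold higher. Heat shock genes had a median of 0.09 at percentile 65.92, with the mitochondrial chaperonin gene HSPD1 2.09-fold lower and HSPA1B, which shares its reads with a near-identical copy, 2.42-fold higher. Autophagy and lysosome genes had a median of 0.32 at percentile 98.16, and CTSD, the cathepsin D gene, was 2.14-fold higher. The percentile came inside the central 95% with unique reads (94.7), the length trend removed (97.12) or the GC trend removed (88.17), and CTSD was below 2-fold under the other scalings.

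All 43 measured cytosolic ribosomal protein genes had a ratio below 1, with a median of -0.67, or 1.59-fold lower, below all 10000 random medians, and none passed 2-fold with library totals. RPL27 was 2.00-fold lower, just short of the limit, and RPL5 1.92-fold lower; with TMM factors RPL27, RPL14, RPL5 and RPL4 were past it, at log2 ratios of -1.163, -1.113, -1.105 and -1.085. Of 50 nuclear genes of oxidative phosphorylation, 48 were below 0 with a median of -0.37, or 1.29-fold lower, below all 10000 random medians; SDHB was 1.95-fold lower, and past 2-fold under the other scalings. Against lists matched on length as well, the oxidative phosphorylation percentile was 3.04, inside the central 95%. All 22 G1/S phase genes were below 0, with a median of -0.47 below all 10000 random medians, and CDT1, a replication licensing gene, was 2.11-fold lower. G2/M phase genes had a median of -0.21 at percentile 7.54, and none of 24 passed 2-fold. DNA damage repair genes had a median of -0.27 at percentile 0.90 with none past 2-fold with library totals; the percentile came inside the central 95% with unique reads (17.92) and with the GC trend removed (2.64). BLM was 1.92-fold lower, and past 2-fold with TMM factors at a log2 ratio of -1.11. Replication-dependent histone genes had a median of 0.73 at percentile 49.24, with 10 of 11 above 0. Their levels were low: the 17 matched genes together held 513 reads in ROSLow and 970 in ROSHigh. The percentile was 99.56 with a minimum of 100 reads, where the median was 2.21, and 99.91 with the authors' RPKM values.

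Interferon response genes had the highest list median with library totals and a minimum of 20 reads, though not with a minimum of 100 reads, the GC trend removed or the authors' RPKM values. All 20 measured members were above 0 and 14 were at least 2-fold higher in ROSHigh, with a median log2 ratio of 1.68, or 3.21-fold, above all 10000 random medians. Levels of the most divergent members were low: OAS2 had 1 read in ROSLow and 56 in ROSHigh (ratio 75.0, interval 12.9 to 3015), MX2 had 2 and 41, and IFI44L had 5 and 61. Immediate early genes had a median of 0.51 at percentile 99.82, with 8 of 21 at least 2-fold higher and 2 at least 2-fold lower; FOSB was 4.28-fold, EGR3 4.11-fold, CTGF 4.03-fold and FOS 3.70-fold higher. Inflammatory genes of the NF-kB list had a median of -0.05 at percentile 21.28 with members on both sides: PTGS2, the cyclooxygenase-2 gene, was 8.99-fold and CCL2 2.95-fold higher, and the growth factor genes CSF3 and CSF2 were 4.66-fold and 3.21-fold lower.

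**Figure D3:**
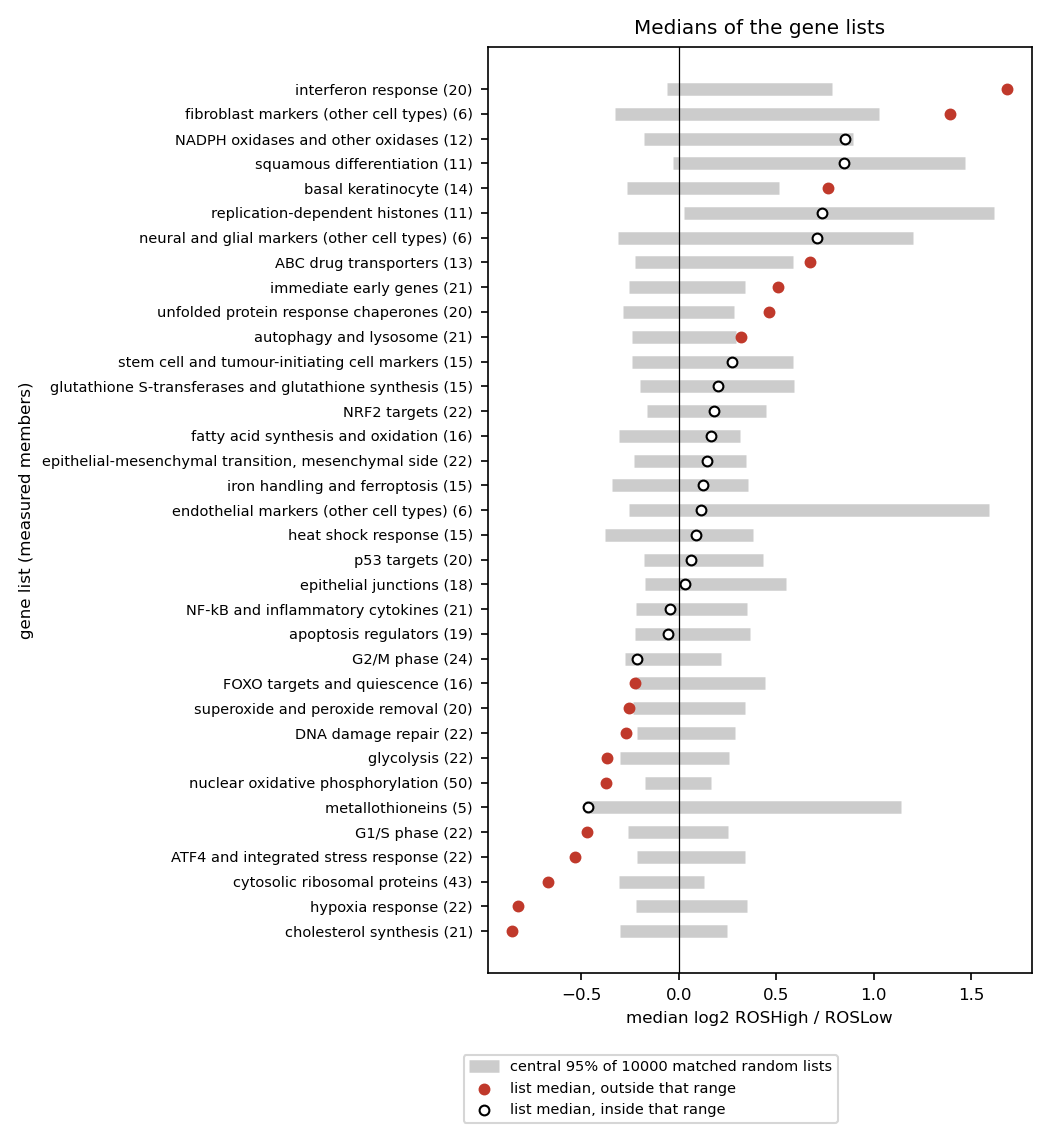
Median log2 ratio of ROSHigh to ROSLow for each gene list, with the number of measured members; red points lie outside and open points inside the central 95% of 10000 random lists matched on expression, drawn as grey bars. Cholesterol synthesis at -0.85 and interferon response at 1.68 mark the ends of the scale.

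Stem cell and tumour-initiating cell markers did not stand apart as a list, with a median of 0.27 at percentile 75.88. Of 15 measured, HES1, a Notch target gene, was 5.71-fold higher in ROSHigh (5.35 to 6.11), ABCG2 3.21-fold higher on 10 and 24 reads, CD24 2.08-fold higher, though below 2-fold under the other scalings, and KLF4 2.60-fold lower. ABC drug transporters had a median of 0.67 at percentile 99.09 with 5 of 13 at least 2-fold higher. Of these, ABCA3 at 2.22-fold was below 2-fold under the other scalings. The percentile of the list was 96.82 with length matched as well and 93.05 with the authors' RPKM values. Basal keratinocyte genes had a median of 0.76 at percentile 99.83, with KRT5 4.69-fold (4.18 to 5.27), CDH3 3.28-fold, TP63 2.88-fold and ITGB4 2.18-fold higher; ITGB4 was below 2-fold under the other scalings. Squamous differentiation genes had a median of 0.85 at percentile 67.4 over 11 measured members of low abundance, among them FLG with 10 and 128 reads, and at percentile 99.79 with unique reads, where the median was 1.40. Mesenchymal genes of the epithelial-mesenchymal transition had a median of 0.14 at percentile 73.62, yet 8 of 22 were at least 2-fold higher and none at least 2-fold lower: COL1A1 was 19.1-fold (17.0 to 21.5), COL5A1 7.47-fold and MMP3 5.69-fold higher. Epithelial junction genes had a median of 0.03 at percentile 22.71, with CDH1, the E-cadherin gene, 5.99-fold higher (5.41 to 6.64) and CLDN4 2.11-fold lower.

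Genes of p53 response, with a median of 0.06 at percentile 37.53, and regulators of apoptosis, with -0.06 at percentile 23.38, lay inside the range of random lists; with unique reads the apoptosis list had a median of -0.35 at percentile 0.50, outside it. TP53I3 and GDF15 were 3.02-fold and 2.65-fold higher, and BBC3 and BCL2 2.95-fold and 2.69-fold lower. FOXO targets had a median of -0.22 at percentile 2.41, with PIK3IP1 and CCNG2 past the limit, and the list came inside the central 95% under 7 alternatives, among them unique reads, where the median was 0.003 at percentile 40.9.

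Markers of other cell types were checked in both fractions. Fibroblast markers were higher in ROSHigh, with a median of 1.39 at percentile 99.7 over 6 measured members, of which PDGFRB at 7.31-fold, FAP at 5.82-fold and COL6A3 at 3.87-fold were past the limit. Endothelial markers had a median of 0.11 at percentile 16.01 and neural and glial markers 0.71 at percentile 82.36, with 27 reads of MAP2 in ROSLow and 424 in ROSHigh. Fewer than 5 members were measured for 3 lists. Of the leukocyte markers, CD14 was 5.01-fold and CSF1R 2.79-fold higher on 157 and 104 reads in ROSHigh, and CD68 was 1.59-fold higher. HBA1 was the only erythroid marker measured, with 44 reads in ROSLow and 28 in ROSHigh, and no mitochondrially encoded gene was among the transcripts analysed.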

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

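The test on olfactory receptor genes was chosen after the result was seen. The share of mapped reads that were not assigned to a listed transcript was 27.71% in ROSHigh (95% Wilson interval 27.702 to 27.727) and 15.97% in ROSLow (15.957 to 15.976), computed from the total behind the RPKM values and the transcript counts. The intervals take the recovered totals as exact and cover counting error only, not variation between library preparations. The unassigned reads enter the report only through the mapped-read totals, which scale 1 alternative and are the denominator of the authors' RPKM values. The share was set beside no control library because the design has none, and which features these reads fall on was not analysed here.

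More genes were higher than lower in ROSHigh, and the excess was concentrated among scarce transcripts, with 1399 of the genes called higher and 164 of those called lower below 10 CPM. Against genomic DNA as a source, 375 olfactory receptor genes, which are not expected to be transcribed in these cells, held at most 0.122 reads per kilobase in ROSHigh (upper 95% Poisson bound), against a median excess of 42.8 reads per kilobase in the genes called higher. For sequencing depth, thinning ROSLow to the total of ROSHigh left 6.16 genes called higher per gene called lower, against 6.19 before. Thinning leaves the expected ratio of each gene as it was, so this checks only the count minimum and the intervals. Whether scaling between the libraries accounts for the size of the excess cannot be told. The number per gene called lower was 2.58 at its smallest over library totals, TMM and DESeq2 factors, between the limits of 1.5 and 3 set in advance. A constant scaling shifts every gene alike, so it does not account for the concentration among scarce transcripts. The median log2 ratio ran from 0.921 in the scarcest decile of genes to -0.064 in the most abundant. A difference in handling between the sorted fractions and a wider range of expressed genes in ROSHigh both stay open and untested, because fraction and library are the same thing in this design.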

How the results depend on the processing

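No paired analysis was possible because each fraction has 1 library, and for the same reason no library could be left out. The total without mitochondrial and ribosomal RNA genes removes nothing here, as none were among the transcripts analysed, and has no value. The mapped-read totals, the trend removals, the 10 CPM minimum, the thinning and the families without list members were chosen after seeing the data. Among the genes named, 121 were past 2-fold; under the other 3 scalings 12 of them came below 2-fold and none changed sign, while 14 named genes that were under 2-fold, all lower in ROSHigh, came past it. Under those scalings 9 of the 35 list medians changed sign, and over all alternatives 13 did. The cause of the following changes was not tested, except that a constant scaling shifts every gene alike and stricter limits leave fewer genes. The authors' RPKM values share the mapped-read totals, so their changes beyond those seen with these totals do not come from scaling. Lower genes numbered 579 with TMM, 610 with DESeq2 factors, 680 with the mapped-read totals, 97 at a ratio of 3 and 165 at 10 CPM; higher genes numbered 372 with the authors' RPKM, 984 at a ratio of 3 and 639 at 10 CPM. With TMM the medians were -0.54 for oxidative phosphorylation, 0.11 for stem cell markers, -0.64 for G1/S, -0.38 for G2/M, -0.10 for p53 targets and -0.83 for ribosomal proteins. With DESeq2 factors they were -0.44 for superoxide and peroxide removal, -0.56 for oxidative phosphorylation, 0.089 for stem cell markers, -0.66 for G1/S, -0.40 for G2/M, -0.12 for p53 targets, 0.32 for immediate early genes and -0.85 for ribosomal proteins. With the mapped-read totals they were -0.47 for superoxide and peroxide removal, -0.09 for iron handling, -0.59 for oxidative phosphorylation, -0.59 for glycolysis, -1.04 for hypoxia, 0.055 for stem cell markers, -0.69 for G1/S, -0.43 for G2/M, -0.15 for p53 targets, 0.29 for immediate early genes and -0.89 for ribosomal proteins. With the authors' RPKM they were -0.10 for NADPH oxidases, -0.10 for iron handling, -0.58 for oxidative phosphorylation, -0.58 for glycolysis, 0.013 for stem cell markers, -0.66 for G1/S, -0.42 for G2/M, -0.16 for p53 targets, 0.17 for ABC transporters, 0.78 for interferon response, 0.16 for immediate early genes and -0.89 for ribosomal proteins. With unique reads they were -0.44 for G1/S, -0.65 for cholesterol synthesis, -0.057 for DNA damage repair at percentile 17.92 and 0.003 for FOXO targets, which changed sign, as did the glutathione list; HMGA1 changed from -1.70 to 0.31. With the length trend removed they were -0.18 for oxidative phosphorylation, -0.44 for G1/S and -0.39 for ribosomal proteins, and with the GC trend removed -0.44 for G1/S and -0.20 for DNA damage repair. The superoxide and peroxide removal list also came inside the central 95% with unique reads (percentile 3.54), the authors' RPKM (15.2), the length trend removed (18.5) and 10 CPM (11.36). Autophagy and lysosome genes did so with unique reads (94.7), the length trend removed (97.12) and the GC trend removed (88.17), ABC transporters with unique reads (93.85), and DNA damage repair with the GC trend removed (2.64). FOXO targets did so under 7 alternatives. In the other direction, metallothioneins, histones, squamous differentiation, apoptosis regulators, NADPH oxidases and iron handling came outside the central 95% under the alternatives the report gives. Cholesterol synthesis, hypoxia, the ATF4 list, G1/S, ribosomal proteins, interferon response, immediate early genes, basal keratinocyte genes, unfolded protein response chaperones and fibroblast markers stayed on their side of the central 95% under every alternative that gave them a value. Depth limits genes with few reads, whose intervals are wide.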

Other observations

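The families in the next 2 paragraphs, the fibroblast test and the genes SMAD6, DUSP4, DUSP5 and DUSP6 were chosen after their values were seen, as were the removal of the length trend and the family medians without list members. The family percentiles, also those without list members, are therefore descriptions and not tests. More families were looked at than are named below, among them zinc finger genes (percentile 98.99), solute carriers (98.38) and HLA genes (63.98). Families of matrix and adhesion genes differed from each other. Of 29 collagen genes, 20 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 ratio of 1.85. Of 13 ADAMTS protease genes, 10 were at least 2-fold higher, with a median of 2.01, and of 21 integrin genes, 12 were, with a median of 1.12. These 3 medians lay above all 10000 random lists matched on expression and on expression with length. The lists of the report already hold 5 of these collagen and 5 of these integrin genes; without them the medians were 1.51 over 24 collagens and 1.26 over 16 integrins, at percentiles 100.0 and 99.85. Claudins, with a median of 0.36 at percentile 53.03, did not stand apart. Laminins had a median of 0.14 at percentile 62.13, but 0.98 at percentile 99.16 over the 7 outside the lists. Keratins had a median of 0.85 at percentile 98.31 and serpins 0.75 at percentile 99.49. Without the 7 keratins and 4 serpins in the lists, the percentiles were 95.35 and 97.47, inside the central 95%. None of these medians except that of the laminins, which is smaller than the shift between scalings, changes sign under the other scalings.

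Among families of protein synthesis and folding genes, the median log2 ratio was -0.51 for 76 mitochondrial ribosomal proteins and -0.51 for 45 nucleolar and ribosomal RNA processing genes. It was -0.40 for 53 eukaryotic initiation factors, -0.38 for 34 aminoacyl-tRNA synthetases and -0.65 for 9 subunits of the chaperonin CCT. Each lay below the 2.5th percentile of random lists, also with length matched. Proteasome subunits had a median of -0.32, and their percentile of 0.04 became 9.25 with length matched. Low medians were not confined to protein synthesis and folding. The median was -0.34 for 20 nuclear pore genes and -0.40 for 21 splicing factor 3 and snRNP genes. With length matched, their percentiles were 0.05 and 1.71.

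The lower ribosomal protein and oxidative phosphorylation genes are short, and shorter transcripts were lower over all genes, these included. Among genes with a mean of at least 10 CPM, the median log2 ratio ran from -0.25 in the shortest decile to 0.26 in the longest. The genes of both lists stayed in these deciles, in the running medians and in the matched random lists. The length comparisons therefore hold part of the lists' own difference, and no trend without these genes was computed. For ribosomal proteins the percentile was 0.01 among lists matched on expression and length, and 0.0 with GC content matched, so neither a length trend nor a GC trend accounts for the whole difference, though removing the length trend took the median from -0.67 to -0.39. For oxidative phosphorylation a transcript length trend cannot be told apart from a difference of these genes, since the percentile was 3.04 with length matched but 1.45 after the length trend was removed, where the median was -0.18; with GC content matched it was 0.0, which argues against a GC trend as the whole cause. The value of 3.04 met the limit set in advance for a length trend as the cause, and the value of 1.45 was set beside it after both were seen. A difference between the fractions in growth state and a difference in RNA fragment recovery by length both stay open, untested, with 1 library each.

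Type I collagen and fibroblast markers were higher in ROSHigh, which could come from fibroblasts in the sorted fraction. COL3A1, DCN and LUM, abundant in fibroblasts, together had 7 reads in ROSHigh, against 4397 reads of COL1A1, which argues against fibroblasts as the source. None of the 6 measured fibroblast markers is in another list. The culture was of SAS cells, an established carcinoma line, and the design names no source of fibroblasts. A higher expression of these genes by the SAS cells themselves remains as the hypothesis, and handling of the sorted fractions was not tested.

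A first hypothesis was that higher ID1, ID3, ATOH8 and SMAD6 (10 reads in ROSLow and 203 in ROSHigh) reflect higher BMP-SMAD transcription in ROSHigh. Of 10 other measured BMP-SMAD targets named in advance, ID2, SMAD9 and DLX3 were 2.16-fold, 2.46-fold and 2.10-fold higher with library totals, and the median lay at percentile 8.64 of matched random lists. Under the other scalings ID2 and DLX3 came below 2-fold, and BAMBI, on 20 reads in ROSLow and 8 in ROSHigh with a counting interval that included 1, came past 2-fold lower. By the limit written in advance, a percentile below 50 counted against the hypothesis. That reading was set aside after the value was seen, because the members went both ways around a median of 0.0. The bootstrap interval of -0.56 to 1.07 resamples the members of the list within these 2 libraries, and genes are not replicates. The test gives no support for the hypothesis and was taken as undecided.

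A second hypothesis was that lower ETV1, ETV4, ETV5, DUSP4, DUSP5 and DUSP6 reflect a lower FGF-ERK transcriptional output in ROSHigh. DUSP4 was 4.84-fold, DUSP5 2.65-fold and DUSP6 2.73-fold lower. The 14 other ERK target genes named in advance had a median of -0.68 at percentile 0.0 of matched random lists, and SPRED1, CCND1, HMGA1 and MAFF were at least 2-fold lower, which is consistent with the hypothesis. The bootstrap interval of this median, again over the members of the list, ran from -1.10 to -0.036. The percentiles of this list and of the BMP-SMAD targets were computed only with library totals, total reads and matching on expression. No alternative was run for them. This test was read by its limit written in advance, although its members also went both ways. HMGA1 was higher with unique reads, which leave out reads shared between transcripts of the gene. PHLDA1 was 1.54-fold higher, and SPRED3, EPHA2 and EPHA4 had log2 ratios of 0.22, 0.30 and 0.31. The immediate early genes FOS, FOSB and EGR3, which ERK signalling also induces, were higher in ROSHigh, so a lower output of the whole pathway is not shown. DUSP5 and DUSP6 were the 2 members of the immediate early list that were at least 2-fold lower. Which signal raised FOS, FOSB and EGR3 was not tested.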
